A study of Mus musculus with 9 samples.

How the data were processed

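RNA was sequenced from primary cultured cortical astrocytes of mouse pups, as 9 libraries in 3 groups of 3 biological replicates by their titles. Controls had 1 day in glucose-free medium. The acetate group had 10 mM sodium acetate for that day. The Aβ plus acetate group had 1 µM amyloid-beta oligomers (Aβ) for 5 days, from day 8 in culture, with acetate in the last day. All cultures changed medium on day 11 and were harvested on day 12. The labels give no group with Aβ and no acetate, so the effect of Aβ alone was not analysed here.

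The deposited values are CPM, counts per 1000000 reads over the listed genes, for 18061 genes in each library. The authors also gave a score for each gene, the CPM minus the gene's mean over its SD in the 9 libraries. The score was recomputed with a largest difference of 4.44e-16 and used for nothing else. The submitters' processing notes name Partek, FastQC, STAR 2.7.3a and the builds mm10 and GRCm39, without saying which build the values rest on. Of 17644 symbols found in the GENCODE M21 annotation of mm10, 17612 (99.82%) overlapped their annotated gene, so positions are given on mm10 as deposited. Stops lay 1 above the annotated end for 6406 genes. No gene on the mitochondrial chromosome was listed, so RNA quality could not be read from mitochondrial transcripts.

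The smallest step between low CPM values implied 22160000 to 57030000 reads per library. Between 93.55% and 94.48% of values up to 20 implied reads were whole to within 0.1, so whole reads were not recovered and no count model was used. Replicates of a group differed by more than counting error.

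Genes with a CPM of at least 1 in at least 3 of the 9 libraries were tested, 14058 in all. Values were log2(CPM + 1), and log2 differences below are on this scale. Groups were compared with limma 3.58.1 in R 4.3.3, two-sided, with a trended and robust prior, no block and all 9 libraries in one fit. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Gene lists fixed from textbook knowledge were tested with camera (limma) at a preset correlation of 0.01, adjusted over the 40 of 42 lists with measured members. Camera with an estimated correlation and fry stand beside it. The lists of mitochondrially encoded transcripts and red blood cell markers had 0 measured members. An exact two-sided permutation of the group labels within library sets, 360 arrangements, was run on list medians.

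Genes were named by 3 rules. The first was up to 10 genes past the threshold in each direction. Where fewer than 5 passed, the 5 with the smallest unadjusted p in that direction were named. The second was up to 4 members of a list with the smallest p. The third was Acss1, Acss2, Acly, Slc16a1, App, Apoe and Gfap whatever their result. Groups, comparisons, lists, naming rules, filters and the first set of alternatives were fixed before the data were examined.

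The numbers in the replicate titles and the numbers in the library names differ. Libraries that share a library-name number deviated from their group means together in 7 of 7 pairs (r across genes 0.761 to 0.947). For the title numbers this held in 7 of 9 pairs (r from -0.842 to 0.947), so the library-name numbers were taken to pair the samples, by a rule that asks for an r over 0.1 in every pair. Each of these pairs lies within 1 library set, and with the set removed the numbers did not pair acetate and Aβ plus acetate in set 2 (r = -0.155), so the number block carries the set and no pairing beyond it was seen. Fits with that number as a block are given beside results they change. Control 1 has no number and stands alone in that fit, so it adds nothing to the comparisons there. Both comparisons with control then rest on control 2 and control 3 only, with 3 residual degrees of freedom.

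The naming style of the library names splits the samples into 2 library sets. Set 1 holds control 1, control 2, acetate 1 and Aβ plus acetate 1. Set 2 holds control 3, acetate 2, acetate 3, Aβ plus acetate 2 and Aβ plus acetate 3. The labels do not say what the sets are. Fits with the set as a covariate, their leave-outs, the fit without acetate 2, the permutations within sets (of list medians and of genes without overlap between groups), and genes picked by their p in the set fit were chosen after seeing the data.

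The other alternatives were pseudocounts, filters on low CPM, median-of-ratios and quantile scaling, limma without trend or robust prior, array quality weights, a block by title number, each comparison's 6 libraries alone, and each of those 6 left out in turn.

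The fits were tested on simulated data with 50 genes shifted at each fold. With no block, a 2-fold shift was recovered in 26% of genes for acetate against control, 30% for Aβ plus acetate against acetate and 42% for Aβ plus acetate against control, with 0 false calls. With the set as covariate, these were 86%, 86% and 96%, with 5, 8 and 5 false calls. List tests were simulated with independent genes and the measured set effects, 20 times. With no block and no change between groups, at least 1 list passed in 20 of 20 simulations for each comparison with control, at 6 to 13 lists with acetate and 6 to 12 with Aβ plus acetate. For Aβ plus acetate against acetate this happened in 2 of 20. With the set as covariate it happened in 2, 0 and 0 of 20.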

Results

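RNA from cultured mouse astrocytes was measured in 3 control libraries, 3 with acetate and 3 with Aβ plus acetate, all after 1 day without glucose. Depth was lowest in control 2, at 22160000 implied reads, and highest in control 1, at 57030000. Between 13504 and 13723 genes per library had a CPM of at least 1. The ribosomal precursor Rn45s took 0.486 to 3.38% of CPM. Because the titles call the samples biological replicates, limma p-values for genes measure the spread between cultures as the labels name them. With no block, that spread includes the difference between the library sets. Camera p-values at the preset correlation rest on the spread between genes and an assumed correlation, not on the spread between cultures.

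The libraries fell into the 2 library sets before they fell into treatment groups. The first principal component held 89.7% of the variance and separated set 1 from set 2. Spearman correlations were 0.992 to 0.997 within sets and 0.905 to 0.935 between them. Stress genes stood far apart between the sets. Ddit3, a transcription factor of the amino acid and unfolded protein responses, had a mean of 16 CPM in set 1 and 685 in set 2. Hspa5, the main chaperone of the endoplasmic reticulum (ER), had 589 and 6720 CPM. Col1a1, a collagen of connective tissue cells, had 359 and 16 CPM. The control group has 2 of its libraries in set 1, and each treated group has 1, so both comparisons with control carry part of the set difference.

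**Figure D1:**
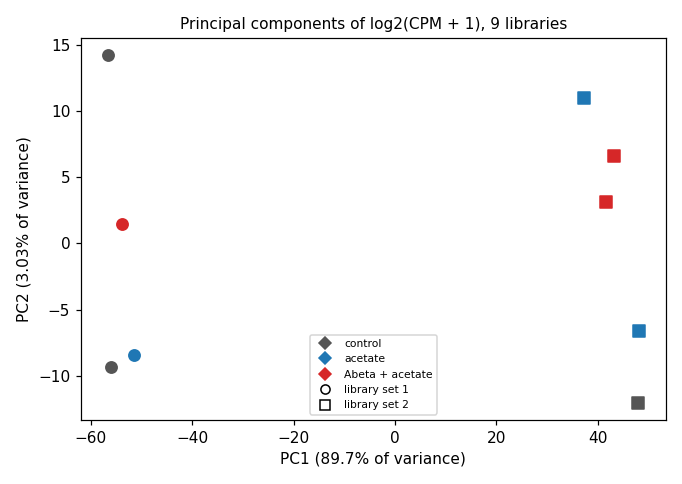
Each point is 1 of the 9 libraries on the first (89.7% of variance) and second (3.03%) principal components of log2(CPM + 1). Colour gives the group, circles are library set 1 and squares set 2, and the sets separate along the first axis while the groups do not.

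The first comparison asked what acetate did to astrocytes kept without glucose. Genes of cholesterol synthesis were lower with acetate, by a median log2 of -0.20 in set 1 and -0.26 in set 2. Lss, which makes lanosterol, had 56.8 ± 2.67 CPM in controls and 43.6 ± 0.701 with acetate (SD, n = 3 each). Fdps, which makes farnesyl diphosphate, had 58.9 ± 13.2 and 39.9 ± 9.68 CPM (SD, n = 3 each). Its log2 difference was -0.55 with no block, against -0.38 in set 1 and -0.34 in set 2. Cell-cycle genes were also lower. Nek2, a mitotic kinase outside the tested cell-cycle list, had 18.1 ± 2.05 CPM in controls and 11.7 ± 1.79 with acetate (SD, n = 3 each).

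All 23 measured genes of cholesterol synthesis and SREBP2 targets had lower means with acetate, and the list fell (median log2 -0.53, camera adjusted p = 2.33e-11). Its adjusted p was 0.686 with an estimated correlation. With the library set as covariate the median was -0.23 (adjusted p = 1.16e-15, and 0.329 with an estimated correlation), with 22 of 23 members lower in each set. The number block moved the median to -0.19 (adjusted p = 1.64e-11). No member passed over all genes. Adjusted over the list alone, 0 members passed with no block, 8 with the number block and 4 with the set covariate. In the set fit, log2 differences were -0.38 (SE 0.08) for Lss, -0.35 (SE 0.08) for Fdps, -0.32 (SE 0.10) for Mvd and -0.28 (SE 0.08) for Nsdhl. Ebp and Cyp51, of the later steps, stood at -0.24 and -0.29 in that fit, and at -0.28 and -0.49 with no block. The permutation within sets gave an exact p of 0.00833 for this list, the smallest of 40, and 0.333 after adjustment. Labels of all 3 groups were shuffled, so this is not a test of acetate against control alone. The smallest exact p that the 360 arrangements can give is 0.00278, which for 1 list alone adjusts to 0.111.

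The cell-cycle list fell as well, with 31 of 31 members lower (median log2 -0.50, camera adjusted p = 8.7e-14, and 0.686 with an estimated correlation). The median was -0.25 with the number block (adjusted p = 3.61e-07) and -0.24 with the set covariate (adjusted p = 2.57e-13, and 0.575 with an estimated correlation). It was -0.34 in set 1 and -0.077 in set 2, where 21 of 31 members were lower. The permutation within sets gave an exact p of 0.0917 for this list (0.937 after adjustment). Members included the mitotic motors Kif11 (log2 -0.44 in the set fit) and Kif20a (-0.44), Cdc20 (-0.38) and Birc5 (-0.40), none of which passed. With no block these were -0.46, -0.71, -0.64 and -0.83, and Birc5 stood at -0.18 within set 2. Ckap2l, a spindle protein outside the list, stood at -0.65.

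Other lists that passed with no block followed the library sets. The amino acid response (ATF4 targets) had a median log2 of 0.74 (adjusted p = 1.36e-06), but -0.046 with the number block (adjusted p = 0.344) and -0.061 with the set covariate (adjusted p = 0.0452). ER chaperones stood at 0.69 (adjusted p = 0.00239), against -0.19 (adjusted p = 1.68e-06) and -0.13 (adjusted p = 0.00041) in those fits. The interferon response stood at 0.45 (adjusted p = 7.86e-05), against -0.017 (adjusted p = 0.988) and 0.017 (adjusted p = 0.401). Extracellular matrix genes stood at -0.77 (adjusted p = 0.00507), against 0.14 (adjusted p = 3.9e-06) and 0.086 (adjusted p = 0.000215). With an estimated correlation, the adjusted p of each of these 4 lists was 0.686 with no block. For the amino acid response, ER chaperones and matrix it was 0.991, 0.89 and 0.89 with the number block and 0.798 each with the set covariate. The set-fit calls of these 3 also ended without control 3 (adjusted p = 0.102, 0.506 and 0.71) or acetate 2 (0.0989, 0.816 and 0.951), and that of the amino acid response without control 1 (0.233) or acetate 1 (0.638). Within set 1 and set 2, the medians were -0.14 and -0.0050 for the amino acid response, -0.13 and -0.13 for ER chaperones, 0.024 and 0.0090 for interferon, and -0.14 and 0.27 for matrix.

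The number block brought 5 further lists past the threshold, all higher with acetate in that fit. Fibroblast and meningeal markers had a median of 0.30 (adjusted p = 0.0014), against -0.48 with no block and 0.34 with the set covariate. Col1a2 stood at 0.50 in the set fit and at -0.48 with no block. Cpxm2, outside the list, stood at 0.37 and -0.086 in those fits. Astrocyte homeostasis stood at 0.074 (adjusted p = 0.00957), fatty acid oxidation at 0.075 (adjusted p = 0.00957), glycolysis at 0.12 (adjusted p = 0.0313) and histone genes at 0.075 (adjusted p = 0.00658). With the set covariate these 4 medians were 0.021, 0.031, 0.049 and -0.033. Within set 1, glycolysis stood at -0.12 with 17 of 21 members lower, fatty acid oxidation at -0.036 with 14 of 22 lower and histone genes at -0.13 with 12 of 16 lower. With an estimated correlation, the adjusted p of each was 0.89. Microglia markers were lower in set 1 (median -1.03, 15 of 15 members) and higher in set 2 (0.23, 13 of 15), standing at -0.23 with the set covariate (adjusted p = 0.0232, and 0.876 with an estimated correlation), with Trem2 at -1.38 in set 1 and -0.030 in set 2 and Tyrobp at -1.08 and 0.027. Without acetate 1 the set-fit microglia median was 0.31, and without control 1 it was -0.13 (adjusted p = 0.406). The set covariate alone passed immediate early genes (median -0.11, adjusted p = 0.00753) and oligodendrocyte markers (0.15, adjusted p = 0.034), each with an adjusted p of 0.798 with an estimated correlation. The list of acetate and acetyl-CoA metabolism had a median of -0.085 (adjusted p = 0.247), and 0.0031 with the set covariate (adjusted p = 0.767). Of the genes named for the treatment, Acss1 stood at -0.092, Acss2, which makes acetyl-CoA from acetate, at -0.31, and Acly at -0.32. The monocarboxylate transporter Slc16a1 stood at 0.45, App at -0.091, Apoe at 0.20 and Gfap at 0.25. With the set covariate these 7 genes were nearer 0 except Acss1, at -0.11 for Acss1, -0.14 for Acss2, -0.16 for Acly, 0.10 for Slc16a1, -0.0015 for App, 0.085 for Apoe and 0.13 for Gfap.

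No gene passed in limma in either direction (smallest adjusted p = 0.936), and 39 genes had an unadjusted p under 0.05 where 702.9 would by chance. Both other fits also called 0, with 668 such genes under the number block and 453 under the set covariate, while array quality weights called 3688 higher and 3663 lower. Groups did not overlap for 304 genes (2.16%). Chance gives 10% for libraries that are alike, and the 360 arrangements of the labels within sets gave 3.18% on average (1.44 to 8.74%). The 5 genes with the smallest unadjusted p in each direction, none past the threshold, were Nat8 (log2 0.59), Ppargc1b (0.48), Car14 (0.66), Arhgap4 (0.50) and Camkv (0.51), and Lss (-0.37), Nek2 (-0.60), Kif11 (-0.46), Bmp3 (-0.61) and Fabp5 (-0.46). In the set fit, Mkln1os at 0.49 was among the highest ranked by p. Lss lies on chromosome 10 from 76531605 to 76557140 and Nat8 on chromosome 6 from 85830387 to 85836858. The scavenger receptor Cd36 had 37.2 ± 6.13 CPM in controls and 23.7 ± 6.44 with acetate (SD, n = 3 each). Of 40 lists, 6 passed with no block, 3 in each direction, 9 with the number block and 11 with the set covariate. With an estimated correlation 0 passed in each of these fits. Fry, counted with no block only, passed 0. In simulations with unchanged groups, the fit with no block passed 6 to 13 lists in 20 of 20 runs. Leaving out 1 library ended the call for ER chaperones (without control 1, control 2 or acetate 3, medians 0.21, 0.31 and 0.20), extracellular matrix (without control 1, control 2, acetate 2 or acetate 3, medians -0.30, -0.36, -0.50 and -0.28) and interferon (without control 1, median 0.22). The cholesterol median was nearer 0 without control 1 (-0.33), control 2 (-0.345) or acetate 3 (-0.32), and farther without control 3 (-0.85) or acetate 1 (-0.83). The cell-cycle median was nearer 0 without control 2 (-0.32) and farther without control 3 (-0.87) or acetate 1 (-0.77). Leave-outs kept both calls in the set fit, with medians of -0.28 to -0.15 for cholesterol and -0.36 to -0.16 for the cell cycle (largest adjusted p = 1.04e-05 and 2.71e-06).

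The second comparison asked what Aβ added to acetate, with medium and acetate the same. This comparison has equal numbers from each library set. Its 3 acetate libraries also serve in the first comparison with opposite sign, so their deviation alone moves a list in opposite directions. In the set fit, cell-cycle medians were -0.24 for acetate against control, 0.20 here and -0.013 for Aβ plus acetate against control. In that order, fibroblast markers had 0.34, -0.29 and -0.076 and immediate early genes -0.11, 0.12 and -0.0059. For these lists, that deviation and 2 separate effects cannot be told apart. Antioxidant genes were higher with Aβ in both sets, where set 1 holds only 1 library of each of these groups. Hmox1, which breaks down haem, had 237 ± 117 CPM with acetate and 348 ± 168 with Aβ (SD, n = 3 each), a log2 difference of 0.66 in set 1 and 0.53 in set 2. Genes of the pan-reactive astrocyte list were also higher, with the protease inhibitor Serpina3n at 175 ± 54.7 and 241 ± 98.4 CPM (SD, n = 3 each). Fibroblast markers were lower in set 2 and not in set 1.

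The NRF2 antioxidant list rose (median log2 0.15, 19 of 22 members higher, camera adjusted p = 0.0021, and 0.126 with an estimated correlation). The median was 0.12 in each set. With the set covariate, the list stood at -0.021 for acetate against control and at 0.14 for Aβ plus acetate against control. In the set fit for Aβ against acetate, Hmox1 stood at 0.57 (SE 0.09) and Srxn1, which repairs peroxiredoxins, at 0.50 (SE 0.10). Slc7a11, the cystine transporter, stood at 0.72 (SE 0.24) and Gclm, of glutathione synthesis, at 0.18 (SE 0.08). Within set 1 and set 2, Slc7a11 stood at 1.59 and 0.29, Srxn1 at 0.50 and 0.50, and Gclm at 0.074 and 0.235. Adjusted over the list alone, 0 members passed with no block and 2 with the set covariate. With no block, the call ended without acetate 1 (median 0.079, adjusted p = 0.106) or without Aβ plus acetate 2 (median 0.11, adjusted p = 0.06), each of which leaves the sets unequal. The set-fit median stayed between 0.10 and 0.18 whichever acetate or Aβ plus acetate library was left out (largest adjusted p = 3.09e-05).

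The pan-reactive astrocyte list rose (median 0.19, 10 of 13 higher, adjusted p = 0.0177, and 0.299 with an estimated correlation), with medians of 0.19 in both sets. Lcn2, an iron-trapping lipocalin, stood at 0.73, Cxcl10 at 0.57 and Hspb1 at 0.53, and none passed. Within set 1 and set 2, Lcn2 stood at 0.465 and 0.87, Cxcl10 at 1.15 and 0.28, and Hspb1 at 0.70 and 0.45. Leaving out acetate 1 (median 0.064), acetate 2 (0.22), Aβ plus acetate 2 (0.15) or Aβ plus acetate 3 (0.087) ended this call with no block, as did testing every gene with a CPM above 0 (adjusted p = 0.13). Leave-outs in the set fit gave 0.18 to 0.29 (largest adjusted p = 0.000565). The A2 list stood at 0.14 (adjusted p = 0.214) and passed with the number block (adjusted p = 0.00156, and 0.439 with an estimated correlation), with Tgm1 at 0.55, Ptx3 at 0.51 and Sphk1 at 0.54. The A1 list did not pass (median 0.086, adjusted p = 0.852). The permutation within sets did not set A1 apart. Its exact p-values were 0.0556 for A1, 0.0667 for the pan-reactive list and 0.0722 for A2 (0.317, 0.321 and 0.321 after adjustment). NF-kB cytokines and chemokines rose (median 0.17, 12 of 15 higher, adjusted p = 0.0256, and 0.391 with an estimated correlation), at 0.20 in set 1 and 0.17 in set 2. Ccl2 stood at 0.93 (1.84 in set 1 and 0.47 in set 2) and Ptgs2 at 0.43 (0.22 and 0.53). With no block, the NF-kB call ended without acetate 1 (median -5.3e-05), Aβ plus acetate 2 (0.049) or Aβ plus acetate 3 (0.083), and with a mean CPM of at least 5 (adjusted p = 0.0558). Leave-outs in the set fit gave 0.11 to 0.21 (largest adjusted p = 0.00367).

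Lysosome and autophagy genes rose by a small amount (median 0.079, 30 of 33 higher, adjusted p = 0.000158, and 0.126 with an estimated correlation), at 0.18 in set 1 and 0.047 in set 2. The lysosomal channel Mcoln1 stood at 0.17. With no block it no longer passed without acetate 1 (median 0.062) or Aβ plus acetate 1 (0.085), or with array quality weights (0.058). The set fit also lost it without acetate 1 (0.054, adjusted p = 0.12) or Aβ plus acetate 1 (0.068, adjusted p = 0.0973). Immediate early genes rose (median 0.12, 18 of 21 higher, adjusted p = 0.00339, and 0.444 with an estimated correlation), at 0.19 in set 1 and 0.013 in set 2, with Fosl1 at 1.06. Without acetate 1 (median 0.065), acetate 3 (0.087) or Aβ plus acetate 1 (0.17), or with array quality weights (0.024), they did not pass with no block. Nor did they in the set fit without the same 3 libraries (0.028, 0.125 and 0.053). Cell-cycle genes rose (median 0.20, 28 of 31 higher, adjusted p = 7.66e-05, and 0.983 with an estimated correlation), at 0.13 and 0.23 in the sets, with Kif20a at 0.52, Aurka at 0.42 and Cdc20 at 0.35. With no block, the cell-cycle call ended without acetate 2 (median 0.11), acetate 3 (0.061) or Aβ plus acetate 1 (-0.027), and the median was 0.47, 0.30 and 0.35 without acetate 1, Aβ plus acetate 2 and Aβ plus acetate 3. With the set modelled, leave-outs gave 0.17 to 0.30 (largest adjusted p = 1.37e-05).

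Fibroblast and meningeal markers fell (median -0.29, 9 of 11 lower, adjusted p = 0.0021, and 0.748 with an estimated correlation), at 0.16 in set 1 and -0.48 in set 2. Of its members, Col1a2 stood at -0.54 and the growth factor Igf2 at -1.41. Slit2, outside the list, stood at -0.46, with -0.85 in set 1 and -0.26 in set 2. With no block, the fibroblast call ended without acetate 1 (median 0.35), Aβ plus acetate 2 (0.11) or Aβ plus acetate 3 (-0.039). Leave-outs in the set fit gave -0.475 to -0.18, nearest 0 without acetate 2 (largest adjusted p = 0.00153). Ependymal and choroid plexus markers fell (median -0.14, 9 of 9 lower, adjusted p = 0.0056, and 0.908 with an estimated correlation), at -0.15 and -0.18 in the sets. With no block they no longer passed without acetate 2 (median 0.0010), acetate 3 (-0.11) or Aβ plus acetate 1 (-0.012), or with every gene above a CPM of 0 tested (adjusted p = 0.185). The set fit lost them without Aβ plus acetate 2 (-0.0070, adjusted p = 0.33). The hypoxia list was lower by camera (adjusted p = 0.0256, and 0.299 with an estimated correlation) with 8 members higher and 8 lower, a median of -0.0058 and a call that ended with the number block (adjusted p = 0.155), the set covariate (adjusted p = 0.16) or any of the 6 libraries left out. Microglia markers stood at 0.96 in set 1, with 15 of 15 members higher, and at -0.51 in set 2, with 15 of 15 lower. The amyloid processing list did not pass (median 0.010, adjusted p = 0.625), with App at 0.033 and Apoe at 0.035. Gfap stood at 0.19, Acss1 at -0.0061, Acss2 at 0.093, Acly at 0.041 and Slc16a1 at -0.069.

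The number block brought 5 lists besides A2 past the threshold. The amino acid response (median 0.064, adjusted p = 0.0023), cholesterol synthesis (0.070, adjusted p = 0.0173) and non-coding RNA (0.10, adjusted p = 0.00213) were higher. Endothelial markers (-0.23, adjusted p = 0.0277) and extracellular matrix (-0.026, adjusted p = 0.0425) were lower. None of these passed with an estimated correlation, where the smallest adjusted p over the lists in that fit was 0.439. The set covariate alone passed pericyte markers (0.073, adjusted p = 0.0408) and microglia markers (-0.11, adjusted p = 0.0361), with 0.592 and 0.789 with an estimated correlation. That microglia call ended without acetate 2 (median 0.065), acetate 3 (-0.024), Aβ plus acetate 2 (0.058) or Aβ plus acetate 3 (-0.12). Without acetate 1 the median was -0.525, and without Aβ plus acetate 1 it was -0.28. For the 8 lists above that passed with no block, hypoxia aside, the permutation within sets gave exact p-values from 0.0333 for the lysosome list to 0.556 for ependymal markers. None passed after adjustment. The smallest of the 40 lists was 0.0222 for heat shock (0.317 after adjustment), which camera did not pass. These 2 groups have equal numbers in each set, so swapping their labels gives the same absolute median. The smallest exact p possible here is therefore above 0.00278, and 1 list alone could not have passed after adjustment.

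**Figure D2:**
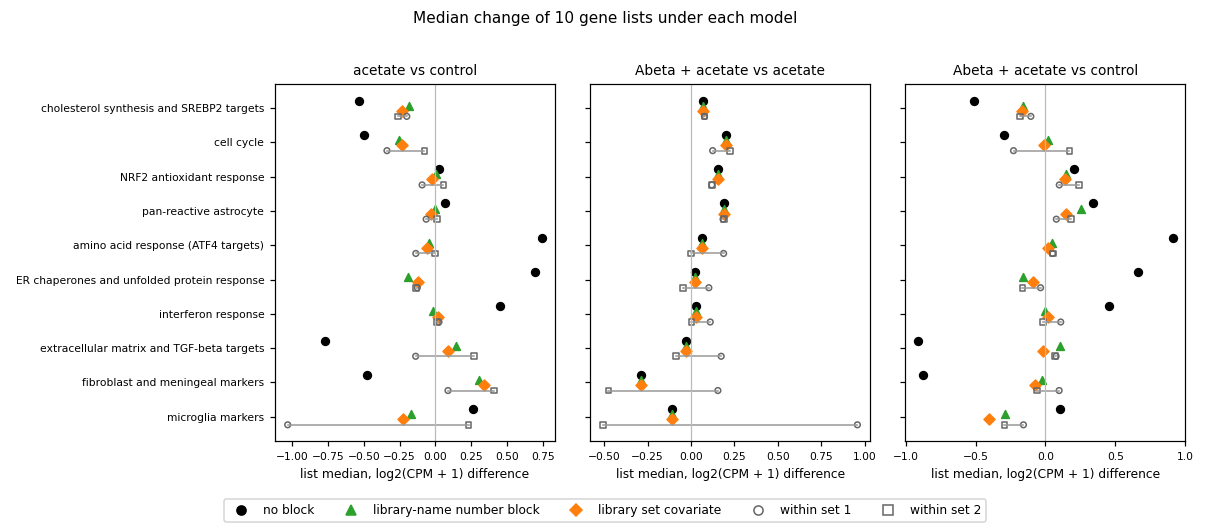
Median log2 differences of 10 gene lists in each comparison, with no block (black circles), the library-name number as block (green triangles), the library set as covariate (orange diamonds) and within library set 1 (open circles) and set 2 (open squares). Cholesterol synthesis lies below 0 in every fit against control, while the amino acid response moves from 0.74 to -0.061 for acetate once the set is in the fit.

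No gene passed in limma for Aβ plus acetate against acetate (smallest adjusted p = 1), with 38 at an unadjusted p under 0.05. The number block and the set covariate also called 0, with 505 and 436 such genes, as did array quality weights with 337. Groups did not overlap for 346 genes (2.46%, against 10% by chance for libraries that are alike and 2.53% on average over the arrangements within sets). The 5 genes with the smallest unadjusted p in each direction, none past the threshold, were Dhrs1 (log2 0.32), Cdo1 (0.36), Wnt7b (0.39), Atp13a4 (0.57) and Tmod1 (0.84), and Adamts18 (-0.56), Rasgrf2 (-0.49), Kcnh5 (-0.42), Cldn2 (-0.47) and Igf2. Dhrs1, a short-chain dehydrogenase on chromosome 14 from 55739020 to 55745685, had 538 ± 32.0 CPM with acetate and 672 ± 9.80 with Aβ (SD, n = 3 each). Adamts18, a metalloprotease gene on chromosome 8 from 113697124 to 113848840, had 2.11 ± 0.112 and 1.11 ± 0.0673 CPM (SD, n = 3 each). Of 40 lists, 9 passed with no block, 6 higher and 3 lower, 14 with the number block and 16 with the set covariate. With an estimated correlation 0 passed in each of these fits, and fry, counted with no block only, passed 0.

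**Figure D3:**
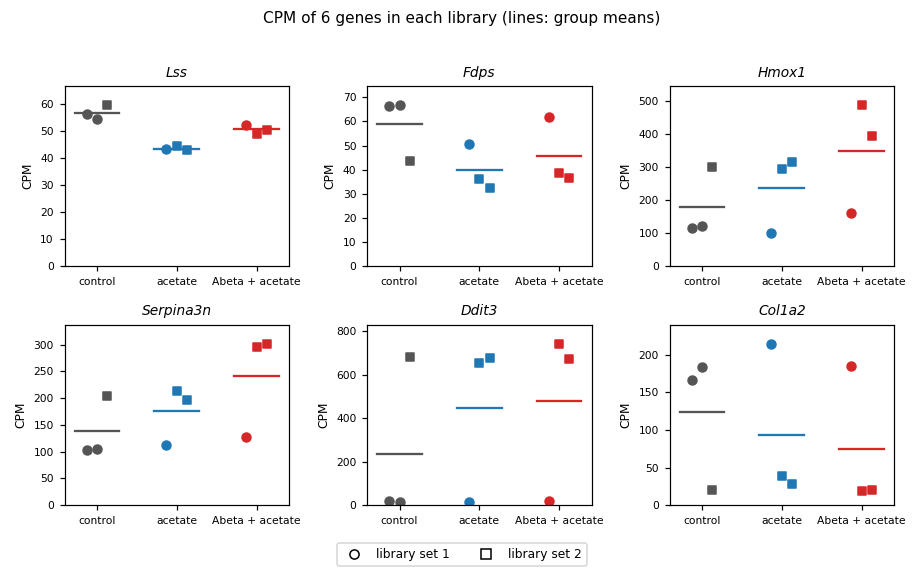
CPM of Lss, Fdps, Hmox1, Serpina3n, Ddit3 and Col1a2 in each of the 9 libraries by group, with lines at the group means, circles for library set 1 and squares for set 2. Lss lies lower in each acetate library (mean 43.6 CPM) than in each control (mean 56.8 CPM), while Ddit3 and Col1a2 separate by set.

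The third comparison set Aβ plus acetate against untreated controls. Cholesterol synthesis genes were lower and antioxidant genes higher, in both library sets, where set 1 holds only 1 Aβ plus acetate library and set 2 only 1 control. Sqle, the squalene epoxidase, had 265 ± 87.7 CPM in controls and 187 ± 78.1 with Aβ plus acetate (SD, n = 3 each). Its log2 difference was -0.51 with no block, but only -0.19 in set 1 and -0.21 in set 2, so these means carry part of the set difference. Tgm1, a transglutaminase of the A2 list, had 11.9 ± 15.3 and 41.7 ± 31.8 CPM (SD, n = 3 each), a log2 difference of 0.60 in set 1 and 1.00 in set 2. Lss stood between, at 50.7 ± 1.72 CPM (SD, n = 3).

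The cholesterol list fell (median log2 -0.51, 23 of 23 lower, camera adjusted p = 1.42e-08, and 0.735 with an estimated correlation). With the set covariate the median was -0.17 (adjusted p = 1.79e-08, and 0.327 with an estimated correlation) and with the number block -0.16 (adjusted p = 2.05e-05). It was -0.11 in set 1 and -0.18 in set 2. With no block it was nearer 0 without control 1 (-0.28), control 2 (-0.31), Aβ plus acetate 2 (-0.31) or Aβ plus acetate 3 (-0.26), and farther without control 3 (-0.825) or Aβ plus acetate 1 (-0.825). In the set fit, Lss stood at -0.17, Sqle at -0.19, Stard4, a sterol carrier, at -0.30 and Nsdhl at -0.19. The NRF2 list rose (median 0.20, 17 of 22 higher, adjusted p = 0.00242, and 0.311 with an estimated correlation), and stood at 0.14 with the set covariate (21 of 22 higher, adjusted p = 4.41e-09) and at 0.099 and 0.24 within the sets. Hmox1 stood at 0.47, Srxn1 at 0.33 and the metallothionein Mt1 at 0.37 in the set fit. With no block, the NRF2 call ended without control 3 (median 0.14, adjusted p = 0.205), without Aβ plus acetate 1 (0.22, adjusted p = 0.0573) or with array quality weights (0.31, adjusted p = 0.228). With the set modelled, leave-outs gave 0.073 to 0.19, lowest without control 3 (largest adjusted p = 2.45e-05). The pan-reactive list rose (median 0.34, 8 of 13 higher, adjusted p = 0.0402, and 0.735 with an estimated correlation), against 0.15 with the set covariate (adjusted p = 3.63e-05), and 0.078 and 0.19 within the sets. Lcn2 stood at 0.79, Serpina3n at 0.44 and Gfap at 0.32 in the set fit, and at 1.10, 0.78 and 0.45 with no block. With no block it no longer passed without control 1 (median 0.15), control 3 (0.42), Aβ plus acetate 1 (0.54) or Aβ plus acetate 2 (0.11), with array quality weights (0.61) or with every gene above a CPM of 0 tested (adjusted p = 0.126). The set fit's leave-outs gave 0.10 to 0.21 (largest adjusted p = 0.0108). The permutation within sets gave exact p-values of 0.0722 for cholesterol, 0.0833 for NRF2 and 0.161 for the pan-reactive list (0.815, 0.815 and 0.871 after adjustment).

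Calls for 7 lists with no block ended or turned in the number block. The amino acid response went from 0.91 (adjusted p = 3.79e-06) to 0.050 (adjusted p = 0.408), and interferon from 0.45 (adjusted p = 0.000208) to -0.0041 (adjusted p = 0.977). The cell cycle went from -0.29 (adjusted p = 3.79e-06) to 0.016 (adjusted p = 0.575), at -0.23 in set 1 and 0.17 in set 2. Fibroblast markers went from -0.88 (adjusted p = 0.0306) to -0.022 (adjusted p = 0.694), and nuclear-encoded OXPHOS genes from -0.083 (adjusted p = 0.0402) to 0.0098 (adjusted p = 0.923). ER chaperones turned from 0.67 (adjusted p = 0.012) to -0.16 (adjusted p = 2.05e-05), and extracellular matrix from -0.91 (adjusted p = 0.000296) to 0.10 (adjusted p = 0.031). For each of these 7, the adjusted p with no block was 0.735 with an estimated correlation, and for ER chaperones and matrix it was 0.855 with the number block. With the set covariate, only ER chaperones among these 7 passed (median -0.091, adjusted p = 0.000465, and 0.649 with an estimated correlation), and it did not without control 3 (-0.069, adjusted p = 0.249). Without control 1, the calls with no block ended for the amino acid response (median 0.44), interferon (0.25), OXPHOS (-0.016), ER chaperones (0.26), fibroblast (-0.55) and matrix (-0.36). Without control 2 they ended for the cell cycle (-0.10), OXPHOS (-0.023), ER chaperones (0.30), fibroblast (-0.48) and matrix (-0.45). Leaving out Aβ plus acetate 2 ended OXPHOS (-0.027), ER chaperones (0.27), fibroblast (-0.44) and matrix (-0.41). Without Aβ plus acetate 3 the same 4 lists ended (-0.025, 0.32, -0.52 and -0.43), as did interferon (0.16).

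Microglia markers stood at 0.11 with no block, at -0.29 with the number block (adjusted p = 0.00803) and at -0.41 with the set covariate (15 of 15 lower, adjusted p = 8.36e-06, and 0.649 with an estimated correlation). They were lower in both sets, at -0.16 and -0.29, and the set-fit median of -0.41 lies beyond both. That fit takes the set difference from all 3 groups. Acetate 1, which stood apart in these markers, was not left out for this comparison. The set-fit median was -0.70 without Aβ plus acetate 1, -0.63 without control 3, -0.24 without control 1 and -0.23 without Aβ plus acetate 2, and the permutation within sets gave an exact p of 0.292. The number block also passed NF-kB cytokines (median 0.17, adjusted p = 0.0363), astrocyte homeostasis (0.13, adjusted p = 0.00803), glycolysis (0.16, adjusted p = 0.00803), fatty acid oxidation (0.097, adjusted p = 0.00912), histone genes (0.15, adjusted p = 0.0122), pericyte markers (0.16, adjusted p = 0.0357) and non-coding RNA (0.11, adjusted p = 0.0363). These 7 medians were, in the set fit, 0.11, 0.067, 0.086, 0.067, 0.036, 0.10 and 0.024. With an estimated correlation, each of these 8 lists had an adjusted p of 0.855 in that fit. The set covariate alone passed astrocyte markers (0.13, adjusted p = 0.00598), ependymal markers (-0.22, adjusted p = 0.0285) and lysosome and autophagy (0.048, adjusted p = 0.0285), with 0.579, 0.649 and 0.649 with an estimated correlation. Acss1 stood at -0.098, Acss2 at -0.22, Acly at -0.28, Slc16a1 at 0.38, App at -0.057 and Apoe at 0.23 with no block. In the set fit they were -0.11, -0.049, -0.12, 0.034, 0.032 and 0.12.

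No gene passed in limma for Aβ plus acetate against control (smallest adjusted p = 0.96), with 61 at an unadjusted p under 0.05. The number block and the set covariate also called 0, with 1145 and 505 such genes, while array quality weights called 5554 higher and 4735 lower. Groups did not overlap for 407 genes (2.9%, against 10% by chance for libraries that are alike and 3.18% on average over the arrangements within sets). The 5 genes with the smallest unadjusted p in each direction, none past the threshold, were Dhrs1 (log2 0.32), Rbm46 (0.64), Fuca2 (0.25), Nat8 (0.53) and Zfp385c (0.45), and Adamts18 (-0.68), Rasgrf2 (-0.72), Ptgfr (-0.54), Ndst3 (-0.44) and Mb21d2 (-0.31). In the set fit the genes with the smallest p included Tgm1 (log2 0.79, adjusted p = 0.339), the peptide receptor Vipr2 (0.50), Slit2 (-0.50) and the vasopressin receptor Avpr1a (-0.53). Of 40 lists, 10 passed with no block, 5 in each direction, 13 with the number block and 12 with the set covariate. With an estimated correlation 0 passed in each of these fits, and fry, counted with no block only, passed 0. In simulations with unchanged groups, the fit with no block passed 6 to 12 lists in 20 of 20 runs.

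Both treated groups were compared with the same 3 controls, which are too few to split. Their log2 differences from control had a correlation across genes of 0.915. Simulating all 9 libraries from their set means, with no change between groups, gave 0.905 (0.900 to 0.910 over 100 simulations). With the set covariate the correlation was 0.546, against 0.537 simulated (0.503 to 0.557). The covariance was 0.0815, against 0.0849 simulated (0.0822 to 0.0870), and the share of genes with the same sign 86.0%, against 85.2% (84.6 to 86.0%). With no block, the correlation lay above its simulated range and the covariance below its own. With the set covariate, the correlation lay inside its range and the covariance (0.00911) below its own (0.00982 to 0.0111). Noise was simulated independently for each gene, so these ranges leave out genes that vary together and cannot decide whether the groups share a change. Overlap of called genes was 0 with 0 expected.

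Across the 3 comparisons, 14 lists passed in none of the fits with no block, the number block or the set covariate, with set-fit medians from -0.076 to 0.086. They were acetate and acetyl-CoA metabolism, fatty acid synthesis, cholesterol efflux and LXR targets, heat shock, A1 reactive astrocyte, synapse-acting secreted proteins, glutamate and GABA metabolism, urea cycle and polyamines, amyloid processing and clearance, complement, histone acetylation and deacetylation enzymes, cytosolic ribosomal proteins, oligodendrocyte precursor markers and neuron markers.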

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

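The set covariate, its leave-outs and the fit without acetate 2 were chosen after the data were seen. Of 1866 values for 99 results of named genes under the alternatives, 1759 kept direction and side of the threshold, 55 passed it under array quality weights, and 52 turned. Of 693 values for 33 list results, 486 kept both, 136 lost the call, 14 gained it and 57 turned. Pseudocounts and the prior without trend or robust step kept each named gene's direction. A mean CPM of at least 5 left 15 of the 99 gene results untested. Counting tools such as edgeR and DESeq2 were not run, because whole reads were not recovered. Median-of-ratios and quantile scaling moved the median of all genes by less than 0.1. Unless stated, the cause of a change was not tested.

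Array quality weights gave acetate against control 3688 genes higher and 3663 lower with 13 lists, and Aβ plus acetate against control 5554 and 4735. The weights ran from 0.157 to 6.46 and were highest for control 2 of set 1 and, at 5.30 and 4.62, for Aβ plus acetate libraries of set 2, so these calls follow the library sets. They turned Mvd (0.11), Trem2 (0.73) and Tyrobp (0.49) for acetate, and Slc16a1 (0.059) and Apoe (-0.021) for Aβ. With median-of-ratios scaling the amyloid list for Aβ was -0.019. Quantile scaling gave it -0.0039, and App -0.0070.

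The replicate block by library-name number gave 0 genes in each comparison and 14 lists for Aβ against acetate (9 with no block). It turned, for acetate, the amino acid response (-0.046), ER chaperones (-0.19), interferon (-0.017), matrix (0.14), fibroblast (0.30), microglia (-0.17), acetate metabolism (0.013), Cpxm2 (0.38), Col1a2 (0.52) and App (0.013). For Aβ plus acetate against control it turned OXPHOS (0.0098), ER chaperones (-0.16), interferon (-0.0041), the cell cycle (0.016), matrix (0.10), microglia (-0.29), Acss2 (0.035), Slc16a1 (-0.0011) and App (0.046). It changed no other call than those printed beside their results. The block by title number, whose numbers do not pair the samples, gave 0 genes and 8, 12 and 12 lists.

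The set covariate gave 11 lists for acetate and 16 for Aβ against acetate. For acetate it turned the amino acid response (-0.061), ER chaperones (-0.13), matrix (0.086), fibroblast (0.34), microglia (-0.23), acetate metabolism (0.0031), Cpxm2 (0.37) and Col1a2 (0.50). For Aβ plus acetate against control it turned OXPHOS (0.012), ER chaperones (-0.091), microglia (-0.41) and App (0.032). Without acetate 2 as well, Aβ against acetate had 15 lists. That fit turned, for acetate, the amino acid response (-0.072), ER chaperones (-0.058), interferon (-0.032), fibroblast (0.20), microglia (-0.45), acetate metabolism (0.0013), Cpxm2 (0.38) and Col1a2 (0.35). It turned microglia for Aβ against acetate (0.065), and for Aβ plus acetate against control OXPHOS (0.014), ER chaperones (-0.10), the cell cycle (0.0070), matrix (0.010), microglia (-0.36) and App (0.034). With the set covariate, the cholesterol median for acetate stayed between -0.28 and -0.15 whichever control or acetate library was left out. The Aβ plus acetate libraries, which also enter the set difference in that fit, were not left out for it.

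With an estimated correlation 0, 0 and 0 lists passed, and with fry, counted with no block only, 0, 0 and 0. Acetate against control fitted on its 6 libraries alone gave 12 lists. Leaving out 1 library gave 0 genes in each comparison and moved the lists between 4 and 13 for acetate, 6 and 14 for Aβ against acetate, and 3 and 9 for Aβ plus acetate against control. The lowest and highest came without control 1 (4) and acetate 1 (13), without acetate 2 (6) and acetate 1 or Aβ plus acetate 3 (14 each), and without control 1 (3) and control 3 or Aβ plus acetate 1 (9 each). Aβ plus acetate against control also had 5 lists without Aβ plus acetate 2, and 6 without control 2 or Aβ plus acetate 3.

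Ranges over left-out libraries crossed 0 as follows. For Aβ against acetate they were -0.11 to 0.19 (Acly), -0.035 to 0.037 (Acss1), -0.081 to 0.23 (Acss2), -0.12 to 0.18 (Apoe), -0.053 to 0.11 (App), -1.59 to 0.35 (Col1a2), -0.74 to 1.58 (Cxcl10), -0.50 to 1.48 (Hspb1), -0.043 to 0.87 (Ptx3), -0.36 to 0.30 (Slc16a1), -0.85 to 1.87 (Slc7a11) and -0.50 to 1.66 (Tgm1). Lists were -0.19 to 0.37 (A1), -0.050 to 0.37 (A2), -5.3e-05 to 0.38 (NF-kB), -0.037 to 0.086 (amyloid), -0.027 to 0.47 (cell cycle), -0.46 to 0.0010 (ependymal), -0.67 to 0.35 (fibroblast) and -0.78 to 0.29 (microglia). For acetate they were -1.48 to 0.081 (Col1a2), -0.55 to 0.18 (Cpxm2), -0.60 to 0.53 (Trem2), -0.52 to 0.36 (Tyrobp), -1.33 to 0.058 (fibroblast) and -0.14 to 0.98 (microglia). For Aβ plus acetate against control they were -0.16 to 0.017 (App) and -0.15 to 0.49 (microglia).

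Depth as a limit was not tested by thinning reads. The median standard error was 0.216 with no block and 0.106 to 0.111 with the set covariate, and in simulations a 1.5-fold shift was recovered for 0 to 6% of genes with no block and 44 to 62% with the set.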

Other observations

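All tests in this part were chosen after the results were seen, and those on glucose and microglia were reworded after their values were seen. The library sets differed in stress genes and in markers of several cell types. With limma, 5394 genes were higher and 4535 lower in set 2 than in set 1, 70.6% of those tested. The amino acid response was higher in set 2, with a median log2 of 2.56 and 35 of 35 members higher. Trib3, Chac1 and Asns, all ATF4 targets, had 2.71, 5.58 and 19 CPM in set 1 and 231, 159 and 287 in set 2. ER chaperones stood at 2.45, with Hsp90b1 at 664 and 4390 CPM. Interferon genes stood at 1.2, microglia markers at 1.59 and ependymal markers at 0.92. Extracellular matrix (-2.58), pericyte (-1.85), fibroblast (-1.67), cholesterol synthesis (-0.94), cell-cycle (-0.78), heat shock (-0.32) and amyloid processing (-0.22) lists were lower in set 2. The smooth muscle actin Acta2 went from 1930 to 299 CPM and Hmgcs1 from 738 to 266. These 12 of 40 lists passed with the preset correlation and 0 with an estimated one (smallest adjusted p = 0.334).

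The difference between the sets was weighed against 3 explanations, none of them named by the design, since the labels give the sets no meaning. A lower share of astrocytes in set 1 would raise the markers of every other cell type there, yet microglia markers were 1.59 higher in set 2, which argues against it as the whole cause. Sex of the pups does not account for it alone, since 9593 of the genes past the threshold are autosomal, although Xist had 370 and 209 CPM and Ddx3y 31.4 and 75.7. Glucose withdrawn more completely in set 2 may be part of it, as the stress lists and Txnip (31.8 and 8.61 CPM) go with it while Arrdc4, a second glucose-responsive gene, was 0.41 higher in set 2. Different preparation or library batch stays open and cannot be told apart from the sets.

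Cholesterol synthesis genes were lower with acetate. Unequal library sets are argued against as the whole cause, since the median was still -0.23 with the set as covariate and of one sign in each set. Chance within the sets stays open, with an exact permutation p of 0.00833 for this list, where 1 list alone could not have passed after adjustment over 40 (0.333, against 0.111 at the smallest). That p shuffles the labels of all 3 groups, not only control and acetate. An effect of acetate itself, the biological explanation the groups give, stays open beside it.

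Genes of the NRF2 antioxidant and pan-reactive astrocyte lists were higher with Aβ. More microglia than in the acetate library may contribute in set 1, where their markers were 0.96 higher and acetate 1 stood apart (mean log2 2.59, against 3.64 and 3.36 in controls and 3.42 with Aβ), but not in set 2, where they were -0.51 and the NRF2 and pan-reactive medians were still 0.12 and 0.19. Chance is not excluded, with an exact permutation p within sets of 0.0556 for the NRF2 list and 0.0667 for the pan-reactive list (0.317 and 0.321 after adjustment). Here too, 1 list alone could not have passed after adjustment, and the labels of all 3 groups were shuffled. A response of astrocytes to Aβ stays open beside these.

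The 6 libraries of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. For genes, 10, 10 and 10 of the 10 splits gave as many as the real 0 for acetate against control, Aβ plus acetate against acetate and Aβ plus acetate against control. Every split must give at least 0, so these shares could not have come out otherwise. The highest gene counts of the other splits were 7089, 0 and 7264. The splits with 7089 and 7264 genes are those that separate the library sets, which points to a structure of the samples, and the fits with the set as covariate gave 0 genes. For lists, 10, 5 and 4 of the 10 splits gave as many as the real 6, 9 and 10, with 14, 15 and 14 at most in the others. Among splits that part as many library-name pairs as the real one, the 3 others gave 8 to 11 lists for acetate against control, 5 to 8 for Aβ plus acetate against acetate and 6 to 8 for Aβ plus acetate against control, and 0 genes. The 6 splits that part fewer pairs gave 6 to 14, 4 to 15 and 6 to 14 lists.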
